A study of Mus musculus with 6 samples.

How the data were processed

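RNA was measured in 6 RPE-enriched libraries, 3 at CT23 and 3 at CT1, grouped by the time point in the sample labels. Per the labels' protocols, the anterior eye was removed and the neural retina peeled off, RPE cells were isolated from the remaining RPE, choroid and sclera by brief sonication, and RNA was extracted with TRIzol. Each library pooled 2 RPE samples and was made with the QuantSeq 3′ mRNA kit. The p-values computed here measure the spread between these libraries. The submitters' processing notes name the mouse build mm10, Bowtie2 2.1.0, HTSeq and edgeR 3.24.1, with no role or order given; filters on genes are not given in the sources used here.

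The deposited table held, per the file headers, CPM for each library, a log2 fold and a p-value. The authors' CPM values were whole multiples of 1 read in 100% of values within 0.01 of a read, which gave library totals of 13651486, 13017532 and 13637470 reads for CT23 replicates 1, 2 and 3 and 13238084, 12612330 and 13505064 reads for CT1 replicates 1, 2 and 3. What these totals count is not given in the sources used here. The listed genes took 12.7% to 32.3% of them. The deposited log2 fold equalled the log2 ratio of mean CPM within 1e-06 in all 14083 entries. The deposited p-value equalled a paired test by replicate number in 12005 entries and an unpaired test with unequal variances in the other 2078, within 1e-06; it was used here only as the authors' value. Of the entries, 75 named no gene and were left out of all tests; they held 0.0432% to 0.102% of the listed reads. The remaining 14008 held 14002 distinct symbols, 13841 of them matched to the GENCODE M21 annotation of mm10, from which coordinates were taken, counted from 1. Every entry was above 0 in at least 4 libraries.

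Because the values were CPM and not counts, the test set for normalized values was used: limma with a mean-variance trend on log2(CPM + 1), over the 11342 genes with a mean of at least 1 CPM, with time as the only factor and Benjamini-Hochberg adjustment, two-sided, at 0.05. Log2 folds are CT1 minus CT23 on this scale and understate the change of low genes. The comparison, its tests, the gene lists, the rule for named genes and the alternatives given first below were set before the data were examined. Since no gene passed, the rule named the 10 smallest p in each direction, all core clock genes, up to 4 members with the smallest p of each other list and the 5 genes with the highest mean CPM over the 6 libraries; other names are marked as chosen after their values were seen. CPM values were not rescaled for composition in limma; TMM factors were 0.963 to 1.03.

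Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over 32 of 34 lists; those of mast cells and erythrocytes had fewer than 3 members tested. Estimated correlations and fry were run beside it. Lists covered the core clock, outer segment phagocytosis, visual cycle, RPE identity, melanin synthesis, lysosome and autophagy, dopamine, melatonin and cAMP signalling, immediate early genes, glucocorticoid response, heat shock, the ER unfolded protein response, fatty acid oxidation, cholesterol synthesis, glycolysis, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, extracellular matrix, cell cycle, inflammation, and markers of rods, cones, Müller glia, inner retinal neurons, endothelium, pericytes, fibroblasts, melanocytes, macrophages, mast cells, erythrocytes, skeletal muscle, Schwann cells and lens. Some genes belong to more than 1 list, such as Per1 (core clock and glucocorticoid response) and Pvalb. Nr1d1, Dbp, Npas2, Best1 and Drd2 were not analysed here, and some genes that the rule names are not reported here.

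Alternatives were other pseudocounts, filters and thresholds, edgeR's quasi-likelihood and exact tests, DESeq2 and limma-voom on the recovered reads, other normalizations, the replicate number as a block, and each library left out in turn. Others were chosen after seeing the data: leaving out the 2 CT23 libraries richest in crystallin reads, TMM factors on CPM, crystallin reads taken out of the totals, edgeR's filterByExpr, an added list of surface epithelium keratins, and oxidative phosphorylation without muscle forms. With a lone CT23 library, limma assumes that it varies like the others. Library pairs differed by more than sampling noise (chi-square per gene 5.17 to 198), so no library was counted as a copy of another. A read was worth 0.0733 to 0.0793 CPM; floors cover counting error only.

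The tests were tried on data simulated for this comparison, with 200 of 11342 genes changed in each of 5 draws. The share of 2-fold changes recovered was 60.2% for limma, 59.2% for edgeR's quasi-likelihood test, 54.6% for DESeq2 and 74.2% for the exact test. Of the calls, 5.81%, 5.14%, 5.58% and 13.8% were false. Camera called 20 of 20 simulated lists of 30 genes shifted by 0.5 and 0 of 600 unshifted ones. Genes were drawn independently of each other in these simulations. They cannot show how often camera falsely calls lists whose genes are correlated. The work used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.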

Results

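The retinal pigment epithelium (RPE) is the pigmented cell layer behind the photoreceptors that takes up their shed outer segments and recycles visual pigment. Gene expression was measured in 6 RPE-enriched libraries from male C57BL/6J mice, an inbred laboratory strain, aged 8 to 10 weeks. Eyes were collected at 2 circadian times, CT23 and CT1, which lie 2 h apart on either side of subjective dawn. Each time had 3 libraries, and each library pooled 2 RPE samples. The libraries were made with a 3′ end kit, in which reads mark the 3′ end of a transcript. The deposited values were CPM, the reads of a gene scaled to a common library size, with library totals that lay between 12612330 and 13651486 reads. The listed genes took 4407650, 3985647 and 1944675 reads in CT23 replicates 1, 2 and 3, and 1676487, 1828912 and 2031337 reads in CT1 replicates 1, 2 and 3. The limit that a count of 0 allows, 3 reads, came to between 0.220 and 0.238 CPM.

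The comparison of CT1 with CT23 addressed how the transcriptome of the RPE differs between circadian times around subjective dawn. Rod photoreceptor genes fell as a group, with all 21 lower at CT1 and a median log2 fold of -0.57. The core clock list fell as well, led by Per2, a repressor of the circadian oscillator, at 3.98 ± 0.630 CPM at CT23 and 1.21 ± 0.418 CPM at CT1 (SD, n = 3 each). Oxidative phosphorylation, fibroblast and skeletal muscle genes rose as groups, with the oxidative phosphorylation sums overlapping between the times. The skeletal muscle sum of CT1 replicate 1 (43.7 CPM) lay near that of CT23 replicate 1 (40.2 CPM). The fibroblast sum was far highest in CT1 replicate 3. Crystallins, the structural proteins of the lens, were concentrated in 2 of the 3 CT23 libraries. These group calls held with a preset correlation between genes and did not pass with an estimated one (adjusted p = 0.458 with an estimated correlation).

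No single gene passed limma's test at an adjusted p of 0.05 among 11342 genes tested, and the smallest adjusted p was 0.0736. An unadjusted p under 0.05 was found for 2469 genes, 1065 higher and 1404 lower at CT1, where 567 would be given by chance. At an adjusted p of 0.1 there were 497 genes, 150 higher and 347 lower at CT1, with a median absolute log2 fold of 0.58. In each of these 497 genes all 3 libraries of one time lay above all 3 of the other. Over all genes tested 3135 (27.6%) were separated in that way, against 10% by chance. On the whole reads recovered from the CPM values, edgeR's quasi-likelihood test gave 0 genes (2464 at an unadjusted p under 0.05) and limma-voom gave 0 (2492). DESeq2 gave 133 genes, 53 higher and 80 lower, and edgeR's exact test gave 813, 368 higher and 445 lower. DESeq2 gave no adjusted p to 5717 of the 11342 genes. Among the 4723 genes with a mean of at least 5 CPM, the smallest limma adjusted p was 0.0489, just under the threshold. There limma gave 98 genes, 15 higher and 83 lower, and the lower ones included 11 rod genes. With crystallin reads taken out of the totals, a setting chosen after seeing the data that moved the median log2 fold of all genes from -0.014 to -0.17, it gave 360 genes differing between CT1 and CT23, with 7 genes higher at CT1 and 353 genes lower at CT1. Without CT23 replicate 3, limma gave 4 genes, all lower at CT1, among them Rspo1, the crystallin gene Crygn and Gm26847, named after their values were seen. Without CT23 replicates 1 and 2, also chosen after seeing the data, it gave 0 genes, and 948 genes with an unadjusted p under 0.05.

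The 10 genes with the smallest p among those higher at CT1 did not pass, each with a limma adjusted p of 0.0736. They were Fuom, Chst5, Met, Ecm2, Emilin2, Cyp1b1, Myzap, Ntn4, Axl and Frrs1. Met, the receptor for hepatocyte growth factor (chromosome 6, 17463800 to 17573980, plus strand), was at 20.3 ± 0.519 CPM at CT23 and 31.0 ± 1.37 CPM at CT1 (SD, n = 3 each; log2 fold 0.59, SE 0.0849). Fuom, which encodes fucose mutarotase (chromosome 7, 140096770 to 140102441, minus strand), was at 1.98 ± 0.140 and 4.60 ± 0.404 CPM (log2 fold 0.91, SE 0.117). Ecm2 and Emilin2, which encode matrix proteins, had log2 folds of 0.98 and 0.72. The 10 genes with the smallest p among those lower at CT1 had the same adjusted p and did not pass. Among them were Mme, Rgs9bp, Grk1, Agpat3, Per2, Opn1mw, Pfkfb2 and Nrl. Rgs9bp, Grk1 (a kinase that acts on visual pigment), Opn1mw (a cone opsin) and Nrl (the transcription factor that sets rod fate) are photoreceptor genes. Grk1 was at 27.5 ± 0.628 CPM at CT23 and 18.3 ± 0.449 CPM at CT1 (log2 fold -0.56, SE 0.0820). Mme, the endopeptidase neprilysin, was at 10.4 ± 1.44 and 4.81 ± 0.701 CPM (log2 fold -0.97, SE 0.137).

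The core clock list fell at CT1, with 15 of 19 members lower and a median log2 fold of -0.17 (camera adjusted p = 0.0160; adjusted p = 0.458 with an estimated correlation). None of its members passed limma's test over all genes tested; adjusted over the list alone, 4 were lower and 1 was higher. At an unadjusted limma p under 0.05, 6 were lower and 1 was higher. Over all genes, edgeR's quasi-likelihood test and limma-voom called 0 members and edgeR's exact test called 3 lower, Per2, Per1 and Rorb, and 1 higher, Bhlhe40. DESeq2 called Rorb alone, as did limma among genes with a mean of at least 5 CPM. Per2 and Per1, with means of 2.60 and 1.41 CPM, lay below that filter and were not tested there. DESeq2 gave no adjusted p to 5717 of 11342 genes, so a gene it did not call may not have been judged. With crystallin reads taken out of the totals, which moved the median log2 fold of all genes lower, limma called 3, Per2, Per1 and Rorb, all lower. Per2 (chromosome 1, 91415982 to 91459324, minus strand) had a log2 fold of -1.18 (SE 0.174). Per1, its paralog (chromosome 11, 69095217 to 69109960, plus strand), was at 1.86 ± 0.122 CPM at CT23 and 0.967 ± 0.0622 CPM at CT1 (SD, n = 3 each; log2 fold -0.54, SE 0.114). Rorb and Rora, nuclear receptor genes of the clock that retinal neurons also express, had log2 folds of -0.59 and -0.39. The higher member was Bhlhe40, a repressor in the clock's feedback loops, at 8.49 ± 0.316 and 11.4 ± 1.57 CPM (log2 fold 0.38, SE 0.113). Arntl and Clock, which encode the positive arm of the oscillator, had log2 folds of -0.12 and -0.068, with limma adjusted p of 0.477 and 0.657. Of the other members, Nfil3, Bhlhe41, Hlf, Cry1, Nr1d2, Per3, Cry2 and Csnk1e had log2 folds between -0.33 and -0.063, and Csnk1d and Tef were at 0.14 and 0.087. The folds of Csnk1d and Tef turned negative with crystallin reads taken out of the totals (-0.048 and -0.080). That setting moved the median log2 fold of all genes from -0.014 to -0.17, so these signs say little about the 2 genes. The fold of Cry2 turned positive without CT23 replicate 1. Ciart, below the filter on low values, was at 0.969 ± 0.0992 and 0.841 ± 0.106 CPM. Rod markers were lower at CT1 in the same libraries, with the median log2 fold given above.

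**Figure D1:**
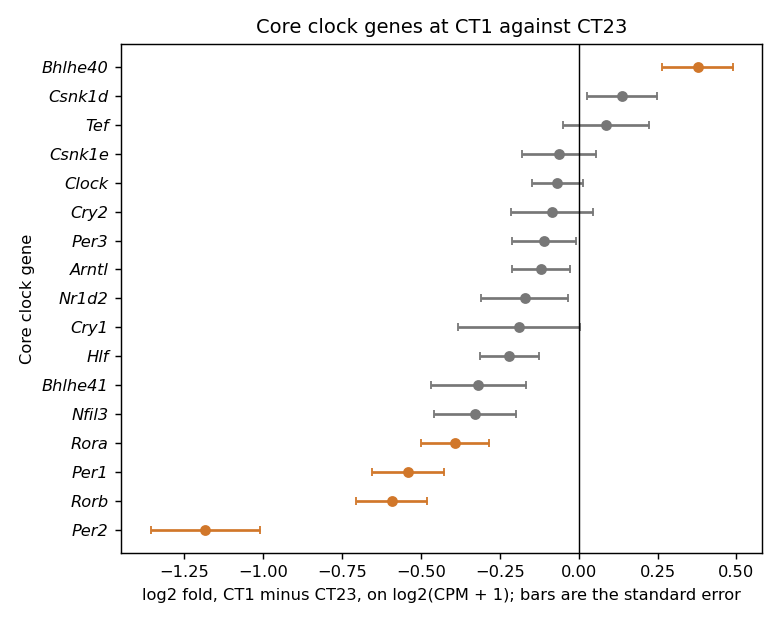
Log2 fold of 17 of the 19 tested core clock genes, CT1 minus CT23 on log2(CPM + 1), from 3 libraries at each time; points are limma estimates, bars are the standard error, and orange marks genes with an adjusted p under 0.05 over the list alone. Per2 lies lowest at -1.18, and 14 of the 17 genes shown lie below 0.

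The outer segment phagocytosis list did not pass (camera adjusted p = 0.175), with 21 of 31 members higher and a median log2 fold of 0.12. None of its members passed limma's test over all genes tested; adjusted over the list alone, 3 were higher and 4 lower. At an unadjusted limma p under 0.05, 5 were higher and 5 lower. By edgeR's quasi-likelihood test and limma-voom 0 members passed over all genes, and by edgeR's exact test 3 were higher, Axl, Mertk and Dock1, and 3 lower, Tub, Tulp1 and Scarb1. Axl alone passed DESeq2 and limma among genes with a mean of at least 5 CPM. Tub, with a mean of 3.39 CPM, lay below that filter and was not tested there. As said above, DESeq2 gave no adjusted p to many genes, so a gene it did not call may not have been judged. With crystallin reads taken out of the totals limma called 2, Tub and Tulp1, both lower. That setting moved the median log2 fold of all genes to -0.17, so it favours lower calls. Axl, a receptor tyrosine kinase related to the engulfment receptor Mertk (chromosome 7, 25757273 to 25788705, minus strand), was at 12.3 ± 1.68 CPM at CT23 and 20.9 ± 2.13 CPM at CT1 (SD, n = 3 each; log2 fold 0.72, SE 0.125). Tub and Tulp1, which are neuronal and photoreceptor genes, had log2 folds of -0.86 and -0.60, and the scavenger receptor gene Scarb1 was at -0.45. The others past the threshold adjusted over the list alone were Mertk (0.44), Dock1 (0.58) and Mfge8 (-0.33), named here after their values were seen.

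Lists for other functions of the RPE did not pass. The visual cycle list had 11 of 12 members higher (median log2 fold 0.22, camera adjusted p = 0.0551; 0 adjusted over the list alone), with Rpe65, the retinoid isomerase, at 88.1 ± 15.6 CPM at CT23 and 108 ± 16.6 CPM at CT1. The RPE identity list had 14 of 19 higher (0.15, adjusted p = 0.0719; 0 adjusted over the list alone), with Serpinf1, which encodes pigment epithelium-derived factor, at a log2 fold of 0.78 and Slc6a20a at 0.44. Melanin synthesis had 8 of 13 higher (0.078, adjusted p = 0.124). Its 1 member past the threshold adjusted over the list alone was Rab38, which routes enzymes to melanosomes, with a log2 fold of 0.55 (SE 0.101). Single libraries moved these calls: without CT1 replicate 3 the adjusted p was 0.00594 for the visual cycle and 0.00501 for RPE identity. Without CT23 replicate 1 it was 0.0131 for the visual cycle and 0.0145 for both RPE identity and melanin synthesis. With each library left out in turn the adjusted p ranged from 0.00594 to 0.465 for the visual cycle and 0.00501 to 0.455 for RPE identity. For melanin synthesis it ranged from 0.0145 to 0.326. Lysosome and autophagy genes had 23 of 38 higher (0.069, adjusted p = 0.284; 0 adjusted over the list alone), with Atg3 at 0.36 and Npc1 at -0.26.

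Among metabolic lists, oxidative phosphorylation rose, with 58 of 71 members higher and a median log2 fold of 0.19 (camera adjusted p = 3.29e-06, adjusted p = 0.458 with an estimated correlation). Its summed expression overlapped between the times. The sums were 1027, 1063 and 859 CPM in CT23 replicates 1, 2 and 3. In CT1 replicates 1, 2 and 3 they were 979, 1233 and 1121 CPM. Adjusted over the list alone 2 were higher, the complex I subunit genes Ndufa5, at 5.54 ± 0.592 and 8.85 ± 0.770 CPM (log2 fold 0.59), and Ndufs4 (log2 fold 0.53). Cox6a2, a muscle form of a cytochrome oxidase subunit, was at 1.58. Without it and 1 other muscle form the list's adjusted p was 9.35e-06. That check cannot exclude muscle RNA, which may also hold the members that remained. Fatty acid oxidation and ketone synthesis rose, with 14 of 18 higher (median 0.12, adjusted p = 0.0242; 1 higher adjusted over the list alone), led by the thiolase gene Acaa2 at 0.59. The call was lost without CT23 replicate 3 (0.0584) or CT1 replicate 2 (0.108). Cholesterol synthesis rose, with 14 of 19 higher (median 0.13, adjusted p = 0.0133; 0 adjusted over the list alone), and Fdps at 1.19 ± 0.368 and 2.50 ± 0.543 CPM (log2 fold 0.68). Glycolysis fell, with 13 of 17 lower (median -0.23, adjusted p = 0.0133; 6 lower adjusted over the list alone), led by the enolase gene Eno1 at 17.5 ± 2.72 and 10.9 ± 2.00 CPM (log2 fold -0.64), with Ldha at -0.35 and Hk2, the hexokinase of photoreceptors, at -0.33. Without CT1 replicate 3 the adjusted p of the glycolysis list was 0.0681, and over left-out libraries it ranged from 0.00574 to 0.0681. Fatty acid oxidation, cholesterol synthesis and glycolysis each had an adjusted p = 0.458 with an estimated correlation. Without CT23 replicates 1 and 2, which left a lone CT23 library, neither the cholesterol synthesis list nor the glycolysis list kept its call. Skeletal muscle markers were higher (median log2 fold 1.19) and rod markers lower (-0.57) in the CT1 libraries. Genes of the surface epithelium of the eye, a list of keratins and others chosen after seeing the data, were also higher (median log2 fold 0.58), and their sums ordered the 6 libraries as the sums of the cholesterol synthesis list did.

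The extracellular matrix list rose, with 21 of 27 members higher and a median log2 fold of 0.34 (camera adjusted p = 0.00377, adjusted p = 0.458 with an estimated correlation). Its sums were 1139, 1155 and 1027 CPM in CT23 replicates 1, 2 and 3. In CT1 replicates 1, 2 and 3 they were 1143, 1216 and 1841 CPM, so the times overlapped and CT1 replicate 3 stood apart. Its members moved both ways: adjusted over the list alone, 5 were higher and 3 lower. Eln, the elastin gene, was at 7.85 ± 0.838 CPM at CT23 and 13.3 ± 2.61 CPM at CT1 (SD, n = 3 each; log2 fold 0.68, SE 0.145), and Lamb2, a laminin gene of basement membranes, and Col3a1 had log2 folds of 0.52 and 0.50. Of the lower members, Col4a1 (chromosome 8, 11198423 to 11312826, minus strand) was at 99.2 ± 35.6 and 40.8 ± 7.08 CPM (log2 fold -1.22, SE 0.240), Col4a2, the other chain of the same basement membrane collagen, was at -0.72, and Nid1, also of basement membranes and named after its values were seen, was at -0.58. The fibroblast and sclera markers, which share Col1a1, Col1a2 and Col3a1 with this list, were higher in the same libraries (median 0.51), and lens markers, with crystallins foremost, were lower (median -3.17). The cell cycle list rose, with 8 of 8 higher (median 0.32, adjusted p = 0.0209; adjusted p = 0.458 with an estimated correlation; 0 adjusted over the list alone). Top2a and Mki67, proliferation markers, were at 0.95 and 0.93. That call was lost without CT23 replicate 2 (0.105), without CT1 replicate 1 (0.116) and without CT23 replicates 1 and 2, which left a lone CT23 library. The summed expression of the cell cycle list was 28.5, 29.1 and 43.2 CPM in CT23 replicates 1, 2 and 3 and 58.2, 36.7 and 48.5 CPM in CT1 replicates 1, 2 and 3. Keratins and other genes of the surface epithelium of the eye, a list chosen after seeing the data, were higher at CT1 too (median log2 fold 0.58), and their sums put the 6 libraries in the same order.

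Signalling and stress lists did not pass. Dopamine, melatonin and cAMP signalling had 17 of 22 members lower (median log2 fold -0.094, camera adjusted p = 0.0860). Adjusted over the list alone 2 were lower, Drd4, a dopamine receptor gene of photoreceptors, at 10.6 ± 1.41 and 6.00 ± 0.576 CPM (log2 fold -0.73, SE 0.123), and Gnai1 at -0.66. Immediate early genes were at an adjusted p of 0.513 (median 0.18; 0 adjusted over the list alone), with Nr4a1 at -1.27 and Klf6 at 0.43. Glucocorticoid response genes were at 0.913, and their median of -0.17 differed in sign from their mean of 0.024 and from camera's direction, which was higher at CT1. Adjusted over the list alone 2 of them were higher and 3 lower, among them the metallothionein gene Mt2 at 0.61, Sgk1 at -0.45 and Per1, which the core clock list also holds. Heat shock and protein folding genes were at 0.267 (median 0.094), with 1 higher, Bag3 at 0.68, and 1 lower, Hspa4l at -0.37, adjusted over the list alone. The ER unfolded protein response was at 0.338 (median 0.040; 0 adjusted over the list alone), with Calr at 0.41 and Atf6 at -0.31. Inflammation and interferon genes were at 0.150 (median 0.16), with 2 higher adjusted over the list alone, Ifitm3 at 0.46 and the complement gene C4b at 0.73. Mitochondrially encoded genes were at 0.235, with 7 of 7 higher and mt-Co1 at 0.29. Cytosolic ribosomal proteins were at 0.0860, with 25 of 39 higher, Rps14 at 0.38 and Rpl31 at -0.54; pseudogene copies make their single values uncertain. The ribosomal list passed without CT23 replicate 3 (0.0486) or CT1 replicate 2 (0.0341).

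**Figure D2:**
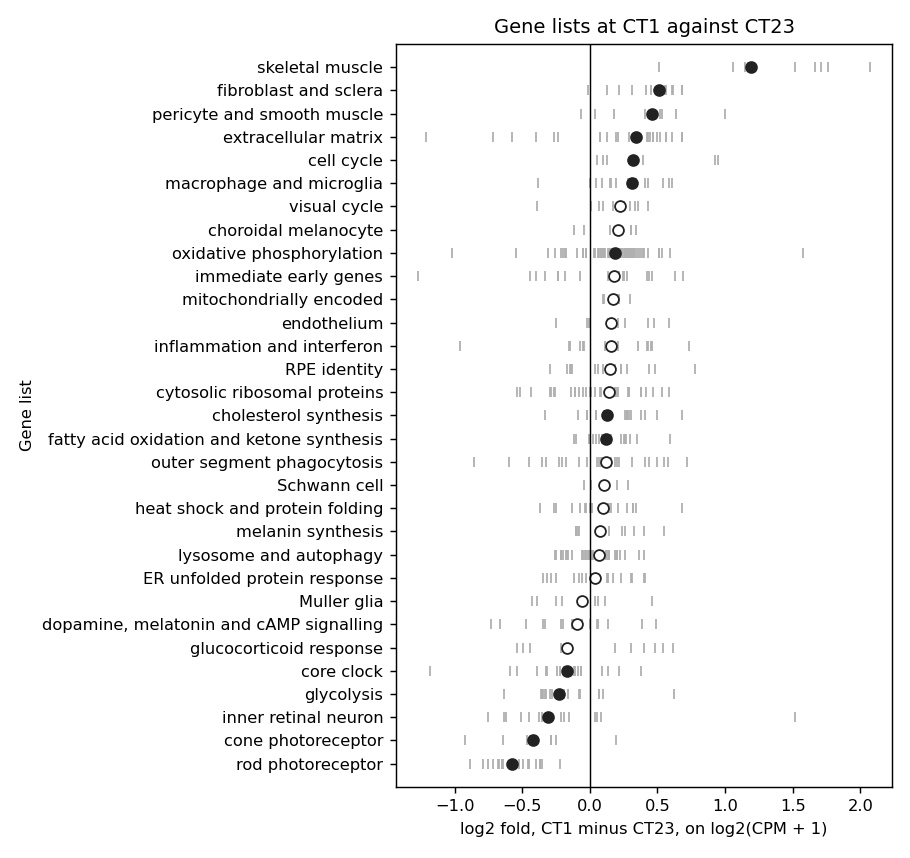
Log2 fold, CT1 minus CT23 on log2(CPM + 1), of the members of 31 gene lists (grey ticks) and the median of each list (circle); filled circles are lists with a camera adjusted p under 0.05 at the preset correlation, and the lens list, with a median of -3.17, is left out. Rod genes have the lowest median shown, -0.57, and skeletal muscle genes the highest, 1.19.

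Markers of retinal neurons were lower at CT1. The rod list fell, with 21 of 21 members lower (camera adjusted p = 8.33e-15; adjusted p = 0.458 with an estimated correlation), of which 0 passed limma's test over all genes tested and 20 adjusted over the list alone. At an unadjusted limma p under 0.05 there were 20. Over all genes, edgeR's quasi-likelihood test and limma-voom called 0 of them, DESeq2 11 and edgeR's exact test 14, all lower. Limma among genes with a mean of at least 5 CPM called 11, all lower. With crystallin reads taken out of the totals limma called 14, all lower. That setting moved the median log2 fold of all genes to -0.17, so it favours lower calls. The summed expression of the list was 1663, 1382 and 1407 CPM in CT23 replicates 1, 2 and 3 and 1002, 1022 and 939 CPM in CT1 replicates 1, 2 and 3. Nrl (chromosome 14, 55518978 to 55524981, minus strand) was at 36.2 ± 3.78 CPM at CT23 and 22.3 ± 0.924 CPM at CT1 (SD, n = 3 each; log2 fold -0.67, SE 0.102). Rcvrn, Rp1 and Pde6a had log2 folds of -0.71, -0.68 and -0.76. The cone list fell, with 8 of 9 lower (median -0.42, adjusted p = 0.00195; 5 lower adjusted over the list alone), and Opn1mw was at 5.20 ± 0.717 and 2.26 ± 0.339 CPM (log2 fold -0.92). The inner retinal neuron list fell, with 11 of 15 lower (median -0.31, adjusted p = 0.00230; 7 lower and 1 higher adjusted over the list alone), and Syt1 and Snap25 were at -0.51 and -0.75. Its higher member, Pvalb, is a skeletal muscle gene too. Cone and inner retinal neuron lists had an adjusted p = 0.458 with an estimated correlation. Müller glia markers did not pass (median -0.061, adjusted p = 0.548, 0 adjusted over the list alone), with Slc1a3 at -0.43 and Car14, which the RPE also expresses, at 0.46. Of the 9 tested, 5 were lower and 4 higher, and at an unadjusted limma p under 0.05, 2 were lower and 1 was higher.

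Markers of skeletal muscle, fibroblasts, pericytes and macrophages were higher at CT1. Skeletal muscle genes rose, with 11 of 11 higher and a median log2 fold of 1.19 (camera adjusted p = 1.50e-06; 10 higher adjusted over the list alone). Their summed expression was 40.2, 38.1 and 10.4 CPM in CT23 replicates 1, 2 and 3 and 43.7, 173 and 125 CPM in CT1 replicates 1, 2 and 3. CT1 replicate 1 lay near CT23 replicates 1 and 2, so the rise rested mainly on CT1 replicates 2 and 3. Tnni2 and Mylpf, genes of fast muscle fibres, were at 1.66 and 1.71. The fibroblast and sclera list rose, with 13 of 14 higher (median 0.51, adjusted p = 1.45e-04, 3 higher adjusted over the list alone), and Clec3b and Dpt were at 0.62 and 0.68. Its sums were 795, 962 and 864 CPM in CT23 replicates 1, 2 and 3. In CT1 replicates 1, 2 and 3 they were 1041, 1054 and 1951 CPM. Without CT1 replicate 3, which stood apart, the camera adjusted p of the list was 0.00594. The pericyte and smooth muscle list rose, with 7 of 8 higher (median 0.46, adjusted p = 0.00843; 3 higher adjusted over the list alone), with Abcc9 at 0.64 and Myl9 at 0.52. The macrophage and microglia list rose, with 15 of 16 higher (median 0.31, adjusted p = 0.00360; 0 adjusted over the list alone), with Cx3cr1 at 0.61 and Lyz2 at 0.54. All 4 lists had an adjusted p = 0.458 with an estimated correlation. Without CT1 replicate 3 the pericyte and macrophage lists did not pass (0.0746 and 0.140).

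Endothelial markers did not pass (median log2 fold 0.16, camera adjusted p = 0.0531; 1 higher adjusted over the list alone, Plvap at 0.43), but did without CT23 replicate 2 (0.0255) or CT1 replicate 1 (0.0102). Choroidal melanocyte markers did not pass (median 0.21, adjusted p = 0.0926; Ednrb 0.30), but did without CT23 replicate 1 (0.0308). Schwann cell markers did not pass (median 0.10, adjusted p = 0.344; Mbp 0.28). Erythrocyte genes Hbb-bt and Hbb-bs, at 0.044 and -0.045, and the 1 mast cell marker measured, Kit, at 0.15, were too few for a list test, and their signs changed with the libraries or the scaling used.

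**Figure D3:**
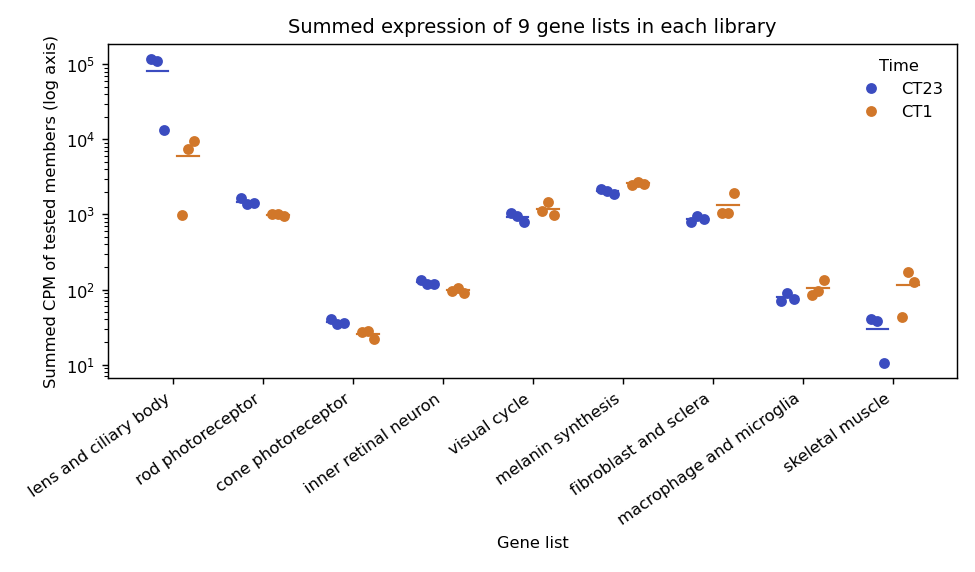
Summed CPM of the tested members of 9 gene lists in each of the 6 libraries, on a log axis; points are libraries, blue for CT23 and orange for CT1, and lines are the means of 3 libraries. The lens list spans 971 to 116800 CPM over the 6 libraries, and the rod list is lower in each CT1 library than in each CT23 library.

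The lens and ciliary body list fell at CT1, with 9 of 11 members lower and a median log2 fold of -3.17 (camera adjusted p = 0.00230; adjusted p = 0.458 with an estimated correlation; 8 lower and 1 higher adjusted over the list alone). The higher member, Wfdc2, named after its values were seen, was at 0.64. The 15 crystallin genes took 19.8%, 18.0% and 2.34% of the library totals in CT23 replicates 1, 2 and 3, and 0.233%, 1.48% and 1.93% in CT1 replicates 1, 2 and 3. Cryba1 (chromosome 11, 77718615 to 77725283, minus strand), the gene with the highest mean over the 6 libraries, was at 32201 ± 24354 CPM at CT23 and 2425 ± 1905 CPM at CT1 (SD, n = 3 each; limma adjusted p = 0.136). That rank rests on CT23 replicates 1 and 2, and in each of the other 4 libraries mt-Rnr2, a mitochondrial ribosomal RNA gene named after its values were seen, was higher. Crygs, Crygb, Cryaa and Crygc, the next by the same mean, had log2 folds of -3.99, -3.13, -4.01 and -3.26. With each library left out in turn these ranged from -5.08 to -2.81, -4.16 to -2.02, -5.03 to -2.97 and -4.35 to -2.12, lowest without CT23 replicate 3 and nearest 0 without CT1 replicate 1. Without both CT23 replicates 1 and 2 they were -1.83, -1.06, -1.97 and -1.10. Gamma crystallin paralogs share sequence, so their single values are uncertain.

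In total 15 of 32 lists passed with the preset correlation, 9 of them higher at CT1, and 0 passed with an estimated correlation. The rotation test fry, which asks whether the genes of a list move on balance in one direction, gave an adjusted p of 0.0341 for the core clock and 0.0390 for rods, and no other list passed it. Its mixed form, which counts changes in either direction, gave an adjusted p of 6.19e-05 for outer segment phagocytosis and 8.23e-05 for glucocorticoid response. Members of both lists moved both ways. The visual cycle (0.368) and RPE identity (0.154) did not pass the mixed form. Neither form compares a list with other genes, and 2469 genes had an unadjusted limma p under 0.05. With CT23 replicates 1 and 2 left out, a lone CT23 library remained, so list calls from that fit cannot separate time from that library. In the authors' deposited table, 1769 of 14083 entries had a p under 0.05, 643 higher at CT1 and 1126 higher at CT23, and 0 passed a Benjamini-Hochberg adjustment of those p-values.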

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

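The settings with crystallin reads taken out of the totals or with CT23 replicates 1 and 2 left out were chosen after seeing the data, as were TMM factors on CPM; the others named here were planned. Among genes with a mean of at least 5 CPM fewer were tested, and the smallest limma adjusted p was 0.0489. There limma's count of 0 genes at an adjusted p of 0.05 became 98 (15 higher, 83 lower at CT1). It became 497 (150 higher, 347 lower) at an adjusted p under 0.1, 133 (53 and 80) with DESeq2 and 813 (368 and 445) with edgeR's exact test, for which 13.8% of simulated calls were false. The exact test and DESeq2 shared 128 genes. With crystallin reads taken out of the totals limma gave 360 genes differing between CT1 and CT23 (7 genes higher at CT1, 353 genes lower at CT1), a setting that moved the median log2 fold of all genes from -0.014 to -0.17. Leaving out each library in turn gave 0 to 4 genes, with 0 to 4 lower, the 4 without CT23 replicate 3. The cause of these changes was not tested otherwise. The 15 lists called by camera became 0 with an estimated correlation, the core clock at an adjusted p of 0.458, and 2 with fry's directional test, which does not compare a list with other genes. With TMM factors on CPM 17 lists passed, the visual cycle list and the endothelium list added, each at 0.0469. The core clock list kept its call with each library left out in turn (0.0128 to 0.0499), and outer segment phagocytosis stayed short of it (0.127 to 0.349).

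Replicate numbers gave no clear sign of pairing. After the mean of each time was subtracted, the correlations of same-numbered libraries were -0.255, 0.383 and -0.0418, and only those numbered 2 correlated best with each other. With 3 libraries at each time, this check cannot show whether same-numbered libraries shared a day or batch. With the replicate block limma gave 0 genes (2480 genes with an unadjusted p under 0.05), edgeR's quasi-likelihood test 0 (2448) and camera 16 gene lists, the visual cycle list (0.0394) added.

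Some lists and genes changed direction. Where libraries were left out or another test or size factor was used, the cause was not tested. The glucocorticoid list did so with fry (adjusted p 0.401), with RLE size factors (0.993), without CT23 replicate 1 (range over left-out libraries 0.802 to 0.955) and without CT23 replicates 1 and 2 (0.846). Immediate early genes did so without CT23 replicate 1 (range 0.148 to 0.860) and without both CT23 replicates (0.277), and Schwann cell markers without CT1 replicate 3 (range 0.142 to 0.998). Over left-out libraries the log2 folds ranged from -0.13 to 0.0037 for Cry2, -0.081 to 0.22 for Hbb-bt, -0.16 to 0.14 for Hbb-bs, -0.11 to 0.11 for Cnp and -0.21 to 0.082 for Pmp22. Without CT23 replicates 1 and 2 they were -0.011 for Ccnd1, -0.11 for Kit, -0.23 for Hbb-bt and 0.11 for Pmp22. With crystallin reads taken out of the totals they were -0.080 for Tef, -0.048 for Csnk1d, -7.8e-04 for Mitf, -0.039 for mt-Nd1, -0.030 for Kdr, -0.0051 for Kit, -0.14 for Hbb-bt and -0.12 for Cnp. That setting rescaled all genes of a library alike and moved the median log2 fold of all genes from -0.014 to -0.17. These signs therefore say little about single genes. Of 164 named folds, 12 changed sign under some setting and 82 had an adjusted p under 0.05 under some setting. Among the 12, Tef, Csnk1d, Mitf, mt-Nd1 and Kdr changed sign only with crystallin reads taken out of the totals.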

Other observations

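The tests of the crystallin, rod and Per patterns and of the keratin list were chosen only after those results were seen; the counts over other splits were planned before. Genes of the surface epithelium of the eye, keratins and desmosome components that the cornea and conjunctiva express, rose at CT1. Of 21 genes tested 19 were higher, with a median log2 fold of 0.58 (camera adjusted p = 1.20e-04 over 33 lists; adjusted p = 0.451 with an estimated correlation). Their summed CPM was 1141, 1727 and 2333 in CT23 replicates 1, 2 and 3 and 3019, 2014 and 2693 in CT1 replicates 1, 2 and 3, lowest in the library richest in crystallin reads. CT23 replicate 3 lay above CT1 replicate 2, so the libraries of both times overlapped. The sums of 3 of the 32 lists, cholesterol synthesis, cell cycle and inflammation and interferon, put the 6 libraries in the same order. Krt15, a basal keratin, had a log2 fold of 0.75, and Pax6, which lens and retina also express, was at -0.0073, both named after their values were seen.

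Crystallin reads were far higher in CT23 replicates 1 and 2 than in the other 4 libraries. Time of day alone is argued against by the pattern itself rather than by a separate test, since it is the same for the 3 CT23 libraries, whose crystallin sums differed 8.46-fold. Lens tissue carried into those libraries is a candidate explanation: over 7 lens fibre genes other than crystallins, the mean of CT23 replicates 1 and 2 had a median ratio of 5.11 to CT23 replicate 3, with the lowest, Prox1, at 1.10. Bfsp1, the most abundant of them, was at 1064, 891 and 161 CPM in CT23 replicates 1, 2 and 3, although the protocol removed the anterior eye (both named after their values were seen).

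Rod genes were lower at CT1. Time of day acting on rod genes alone is argued against, because cone and inner retinal neuron genes were lower too. Without Pvalb, left out as a muscle gene too, the median edgeR log2 fold of 23 such genes was -0.42. Its upper 95% bound was -0.28 from resampling genes as if independent. The rotation test fry, which allows for correlated genes, gave an unadjusted p = 0.00481 for this set, which was merged after seeing the data. The planned cone and inner retinal neuron lists, Pvalb included, did not pass fry (adjusted p = 0.0584 and 0.0577). A lower share of RPE RNA at CT23, raising every other tissue alike, is argued against as the only cause. Rod and fibroblast sums moved apart, and the lowest CT23 ratio of the 2 was 1.48 times the highest CT1 ratio. If fibroblast carry-over also varied between libraries, this ratio cannot decide, and such a share stays open as a part. It would lower RPE genes at CT23, where 11 of 12 visual cycle and 8 of 13 melanin synthesis genes were lower, though neither list passed. Less neural retina RNA in the CT1 libraries stays open. Gnat1, the rod transducin gene, was at 129.7 ± 15.6 CPM at CT23 and 82.4 ± 5.33 CPM at CT1 (SD, n = 3 each; named after its values were seen). Müller glia genes, which less retina RNA would lower too, had a median edgeR log2 fold of -0.046 with 4 of 9 higher. Their 95% interval, from resampling genes as if independent, ran from -0.44 to 0.13. It includes 0 and lies above the rod median of -0.60. At an unadjusted limma p under 0.05, Slc1a3 and Aqp4 were lower and Car14 was higher. Some of these genes, such as Car14, are also expressed by the RPE. Regulation by time of day across retinal neurons stays open as well, as it was not tested.

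Per2 and Per1 were lower at CT1, and the retina expresses both. Carried-over retina RNA alone, at a fixed level of the gene per retina, and a change of their own cannot be told apart: the edgeR log2 folds of Per2 and Per1 had upper 95% bounds of -0.96 and -0.40. The Per2 bound lay below the rod median of -0.60, but retina genes fell unequally, and the bound lay above the lowest of their edgeR log2 folds, -1.18 for the cone opsin gene Opn1mw. The Per1 bound lay above both values. A time-of-day difference in the RPE, in the retina or in both stays open for both genes, untested.

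The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. At an adjusted p under 0.05 the real split gave 0 genes and the highest other split 0, so all 10 gave as many. At an adjusted p under 0.1 the real split gave 497 and the highest other 0, so 1 of the 10 splits gave as many. At an unadjusted p under 0.05 it gave 2469 genes, with 1471 as the highest other, again 1 of 10. For gene lists it gave 15, and the split that put CT1 replicate 1 with CT23 replicates 1 and 2 also gave 15, so 2 of 10 gave as many.

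The CPM of listed genes other than crystallins summed to 125289, 126500.1 and 119239 in CT23 replicates 1, 2 and 3 and 124312, 130192 and 131132 in CT1 replicates 1, 2 and 3, so CT23 replicates 1 and 2, rich in crystallin reads, lay within the range of the other 4. In the authors' deposited table the p-value came from a paired test for 12005 entries, of which 99.9% of those matched were protein coding, and from an unpaired test for 2078, of which 0.728% were.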
